A study of Mus musculus with 4 samples.

How the data were processed

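RNA-seq of polyadenylated RNA was deposited for 4 libraries of sorted mouse cells, 2 of GFP+/RFP+ cells (EC-OSB) and 2 of RFP+ cells outside that population. Per the labels' protocols, 1.3 ug of total RNA per library was enriched for poly(A) RNA, made into strand-specific libraries by the dUTP method and sequenced from both ends for 150 cycles. The deposited table holds whole-number counts per gene, not normalized, for 39179 Ensembl gene identifiers, of which 37607 have a symbol in the GENCODE M21 annotation used here. Per the submitters' processing notes, the tools named are STAR 2.6.0b, HTSeq, RSEM and Bowtie2 2.2.3 and the builds named are mm10 and GRCm38. Which of these tools made the counts, the annotation release and the strand setting of the counting are not given in the sources used here.

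All identifiers in the table were Ensembl genes, and 0 entries held anything else. Identifiers without a symbol took 0.292% to 0.348% of a library's counts, and the 20 most abundant genes 10.6% to 11.3%. One count equals about 0.0169 to 0.0182 CPM. Where the libraries of a group had 0 counts, folds were set against a floor of 3 counts over the group (0.0254 CPM in EC-OSB, 0.0271 CPM in RFP+), and where they had 1 to 3 counts a ratio with its 95% counting interval is given. Floors and intervals cover counting error only. Gene positions are from GENCODE M21 on GRCm38. Each value belongs to a gene as a whole and does not separate exons, introns or UTRs.

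Reads from overlapping genes may be dropped or misassigned in such a table. Among the genes named, those whose exons overlap a gene on the opposite strand are Acvrl1, Ank1, Atp5a1, Bmp6, Cd34, Cebpa, Csf1r, Eng, Fcna, Hk1, Il1b, Junb, Lcp1, Lef1, Mcam, Mpo, Nid2, Notch1, Pdia6, Pi16, Prtn3, Reln, Runx2, Slc25a37, Sox4, Sphk1, Stab2, Tpi1, Trim7, Vcam1, Zfp36, mt-Co1 and Gm42418. Ank, Cd74, Ifitm5, Itgam, Notch2, Rag1, Spp1, Top2a and mt-Nd1 overlap a gene on the same strand, and Hsp90b1, Pfkm and Plod3 overlap genes on both. Their counts are uncertain to that extent. The same holds for genes with near-identical copies, such as the globin genes, the osteocalcin genes, MHC class II genes and mitochondrial genes with nuclear copies. Snai2, Twist1, Bmp4 and mt-Atp6, which are named below, were not looked up for overlaps.

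Differential expression was tested with the edgeR 4.0.16 quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest; R 4.3.3) on the deposited counts, with TMM factors (1.018 and 1.019 in EC-OSB, 0.981 and 0.983 in RFP+). Genes were kept by filterByExpr at its defaults (a minimum count of 10, a minimum total of 15), which left 15909 of the 23918 genes with any count. The model compared the groups without other terms, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Levels are CPM on TMM-scaled library sizes. Standard errors belong to log2 fold changes.

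For 39 gene lists of cell types, pathways and cell states, the members called were counted over all tested genes and again with p-values adjusted over the list alone; the counts were the same except for the angiogenic ligands. Lists with at least 5 tested members (37 of them) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over lists. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the members of a list changed, without setting them against other genes. The genes named are Col1a1 and Tek; the 12 with the largest increase and the 12 with the largest decrease among called genes with separated libraries and a mean of at least 10 CPM in the higher group, leaving out unnamed gene models; per list, the 3 called members with the smallest p and the 2 most abundant uncalled ones, not all printed, and 3 of the genes so picked are not reported here; a fixed panel of osteoblast, endothelial and blood genes; and the 5 most abundant genes of each group. The groups, tests, lists, the rule for named genes and the alternatives listed next were set before the data were examined. Col1a1 is in no list.

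Alternatives were DESeq2 1.42.0, limma-voom, upper-quartile factors, library totals without TMM, no filter, a filter of 5 CPM in 2 libraries, glmTreat against 1.5-fold, library sizes without the 20 most abundant genes, the replicate number as a block, and each library left out in turn. Assumed coefficients of variation of 10% and 20% and offsets for GC content and transcript length (a loess trend with a span of 0.5) were added after seeing the data.

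The test was tried on simulated counts for EC-OSB against RFP+, with 15847 genes tested and 200 changed. Means were those of the real libraries, and every gene had the same spread, the median coefficient of variation of 4.66%. The test recovered 20.0% of genes changed by a log2 of 0.25, 81.2% at 0.5, 92.0% at 1 and 97.9% at 2, and 6 of 148 calls (4.05%) were false. In the data 67.2% of genes were called, so these rates hold for a setting with far fewer changed genes. Figures were drawn with matplotlib 3.10.9. The sequences of the GFP and tdTomato transgenes were not analysed here.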

Results

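RNA was sequenced from 2 sorted populations of mouse cells that carry a Col1a1-GFP reporter, Tie2-cre and a Rosa-tdTomato reporter. Tie2-cre expresses the recombinase from the promoter of Tek, a receptor of endothelial cells whose promoter is also active in blood-forming cells, so endothelial cells, blood cells and their descendants carry the red label. Col1a1 encodes the alpha 1 chain of type I collagen, the main collagen of bone, and its reporter marks cells of the osteoblast lineage and other collagen producers in green. The EC-OSB group holds cells with both labels (GFP+/RFP+), and the RFP+ group holds red cells that the labels set apart as not EC-OSB. Each group has 2 libraries. The tissue, the age of the mice and the sort gates are not given in the sources used here. The deposited gene counts summed to 57847605 and 58024482 in the EC-OSB libraries and to 56078648 and 56555945 in the RFP+ libraries, and between 20870 and 21109 genes had at least 1 count in a library.

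The comparison asked how double-labelled cells differ in gene expression from red cells outside that gate, in a study of endothelial cells that become osteoblasts. Genes of the bone matrix were far higher in EC-OSB, as a gate on a Col1a1 reporter would favour. Col1a2, the partner chain of type I collagen, stood at 372 ± 0.871 against 0.208 ± 0.0369 CPM (mean ± SD, n = 2 libraries per group, as for all levels here). Sparc, a collagen-binding protein of bone, stood at 74.0 ± 0.103 against 0.262 ± 0.0402 CPM. Genes of red blood cell precursors and of tissue-resident macrophages were also higher, among them the red cell membrane protein gene Slc4a1 (164 ± 2.32 against 24.1 ± 0.655 CPM) and the complement gene C1qa (45.0 ± 1.02 against 2.30 ± 0.144 CPM). Genes of B cells were lower, such as Cd79b, a part of the B cell receptor, at 79.1 ± 1.96 against 303 ± 6.03 CPM. Transcripts of neutrophils were among the most abundant of both groups, and S100a9 reached 12251 ± 10.9 against 16751 ± 92.9 CPM.

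The genes behind the reporters were compared first, as a check of the labels. Col1a1 (ENSMUSG00000001506; GRCm38 chromosome 11, 94936224 to 94953042, plus strand) was measured at 533 ± 2.05 against 5.17 ± 0.271 CPM, a log2 difference of 6.69 (SE 0.0276). This follows from the gate and is not a finding. Tek (ENSMUSG00000006386; chromosome 4, 94739289 to 94874976, plus strand) was low in both groups, at 1.08 ± 0.440 against 0.587 ± 0.188 CPM, with a log2 difference of 0.87 and an adjusted p of 0.0211 (edgeR quasi-likelihood test). That call was lost without EC-OSB replicate 2 (0.38, adjusted p = 0.482) and without RFP+ replicate 1 (0.58, adjusted p = 0.200). It was also lost under DESeq2 (adjusted p = 0.107) and limma-voom (adjusted p = 0.0678).

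Libraries of a group resembled each other more than libraries of different groups. Pearson's r of log2 CPM across the tested genes was 0.993 between the EC-OSB libraries and 0.992 between the RFP+ libraries, and 0.964 to 0.965 across groups. These correlations are across genes, which are not independent replicates. The first principal component, which separated the groups, held 81.2% of the variance. Replicates nonetheless differed by more than sampling noise, with a chi-square per degree of freedom of 4.34 in EC-OSB and 3.64 in RFP+, against 172 to 175 across groups. This excess speaks only against the same library deposited under both names. Each library was counted as a replicate. The labels do not say that replicates came from separate animals or sorts, and p-values therefore measure only the spread between these libraries, which may be technical.

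Of 15909 genes tested, 10684 (67.2%) differed between EC-OSB and RFP+ cells at an adjusted p under 0.05, of which 5650 were higher in EC-OSB and 5034 lower. Large differences lay mostly on the EC-OSB side, with 407 genes at least 4-fold higher and 139 at least 4-fold lower. At least an 8-fold difference was met by 217 higher and 23 lower genes. With the 30 called genes at 0 counts in either group set to their bounds, 216 were higher and 23 lower by that much. At least a 2-fold difference was met by 956 higher and 1010 lower genes, or by 652 and 628 of them among genes with a mean of 1 CPM or more in the higher group. Both libraries of a group lay on the same side of both of the other in 13085 genes (82.2%), where chance gives 33.3%. The common biological coefficient of variation was 4.71%, and 6395 of the calls (59.9%) were differences under 1.5-fold. A test against a difference of 1.5-fold (glmTreat) called 2632 genes, and an assumed coefficient of variation of 20%, added after seeing how alike the replicates were, left 2789.

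**Figure D1:**
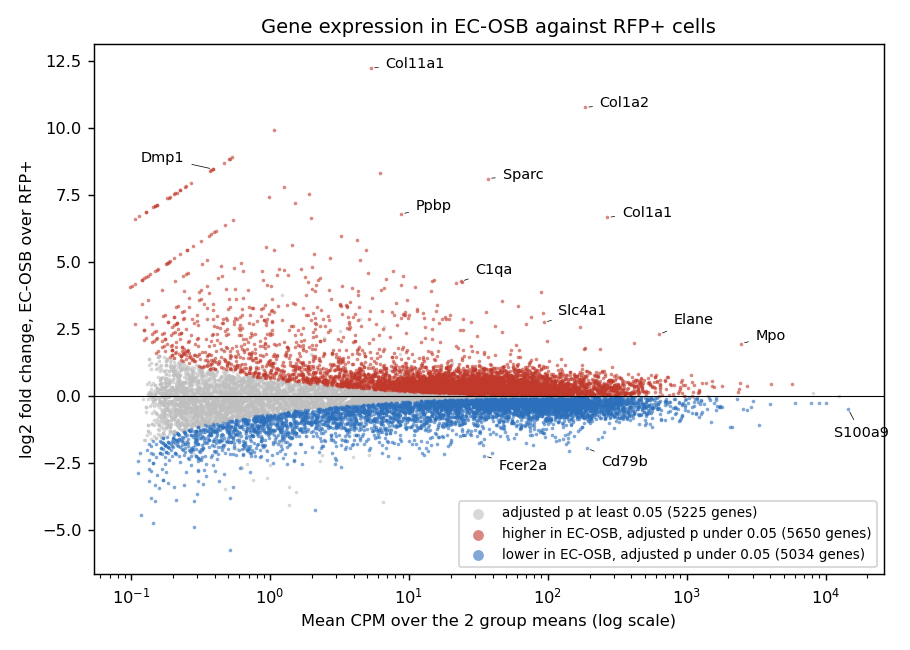
Each point is a tested gene, with the mean CPM of the 2 groups on a log axis and the fitted log2 fold change of EC-OSB over RFP+ on the other. Red points (5650 genes) were higher and blue points (5034) lower in EC-OSB at an adjusted p under 0.05, and grey points were not called. Collagen genes lie at the top, and the diagonal streaks at low CPM are genes with 0 or 1 counts in RFP+, whose fitted values depend on the prior count.

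Bone and connective-tissue collagens, which the gate on the Col1a1 reporter would also favour, led the genes higher in EC-OSB. Of the 12 genes with the largest increase and a mean of at least 10 CPM in EC-OSB, Col1a1 itself aside, Col1a2 (ENSMUSG00000029661; chromosome 6, 4504814 to 4541544, plus strand) had the largest measurable log2 difference, 10.79 (SE 0.0476). Col11a1 (ENSMUSG00000027966; chromosome 3, 114030540 to 114220718, plus strand), a minor fibril-forming collagen, had 659 and 601 counts in EC-OSB and 0 in both RFP+ libraries. It was at least 394-fold higher against a floor of 3 counts over the group. Col5a2, a further fibril collagen, had a log2 difference of 8.33 (SE 0.241), or 9.24 without RFP+ replicate 2, on very few RFP+ counts. Sparc (ENSMUSG00000018593; chromosome 11, 55394500 to 55423183, minus strand) differed by 8.13 (SE 0.0872) and Col14a1, a fibril-associated collagen, by 4.68 (SE 0.141). The others in this group were Ppbp, a platelet chemokine precursor (6.81), Sphk1, a sphingosine kinase (4.51), and the macrophage genes Mertk, a receptor for the uptake of dying cells (4.40), Fcna (4.34), Cd5l (4.31) and C1qa (4.29). Adjusted p-values of these genes, Col1a1 aside, lay between 1.8e-92 and 1.7e-38 (edgeR quasi-likelihood test).

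The 12 genes with the largest decrease changed less and were of several kinds. Fcer2a and Cr2, receptors of mature B cells, had log2 differences of -2.22 (SE 0.0480) and -2.17. Rag1, which cuts antigen receptor genes in developing lymphocytes, was at 55.7 ± 1.71 against 228 ± 4.46 CPM, and Cd79b (ENSMUSG00000040592; chromosome 11, 106311341 to 106314762, minus strand) had a log2 difference of -1.94 (SE 0.0221). The voltage-gated channel genes Scn4a (-2.28), Scn4b (-1.93) and Cacna1i (-2.15) were lower in EC-OSB too. So were Trim7 (-2.23), the phosphodiesterase Pde4c (-2.11) and the extracellular glycoprotein Reln (-2.11). The collagens Col5a3 (14.7 ± 0.184 against 64.2 ± 0.625 CPM) and Col27a1 (5.49 ± 0.0316 against 20.9 ± 0.530 CPM) went against the direction of the other collagens named. Adjusted p-values of these 12 genes lay between 2.4e-64 and 2.1e-23.

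Genes of osteoblasts rose as a group, although not in every member. The Col1a1 reporter used for the gate marks cells of the osteoblast lineage, so the gate would favour such a rise. Of 19 tested osteoblast genes, 14 were higher and 2 lower in EC-OSB. Their median log2 difference was 1.53 (camera adjusted p = 0.000135, or 0.304 with an estimated correlation). The list held 0.0628% of counts in EC-OSB and 0.0153% in RFP+. Most of the EC-OSB share came from Col1a2 (372 against 0.208 CPM) and Sparc (74.0 against 0.262 CPM), so it does not describe the other members. Ibsp, a mineral-binding matrix protein, was at 9.58 ± 0.187 against 0.216 ± 0.152 CPM, a log2 difference of 5.45 (SE 0.225), or 6.43 without RFP+ replicate 2. Sp7, a transcription factor required for osteoblasts, had 47 and 48 counts in EC-OSB and 0 and 1 in RFP+, a ratio of 89.1 (95% counting interval 15.6 to 3555). Its fitted log2 difference moved from 6.17 to 5.32 without RFP+ replicate 1 and to 8.54 without RFP+ replicate 2. Runx2, the transcription factor that starts the lineage, was abundant in both groups and slightly lower in EC-OSB (93.7 ± 4.73 against 104 ± 0.196 CPM; log2 difference -0.14, or -0.09 without EC-OSB replicate 1). Spp1 was at 19.3 ± 0.525 against 12.2 ± 0.0810 CPM, and the alkaline phosphatase gene Alpl at 7.73 ± 0.241 against 6.47 ± 0.0570 CPM. The Alpl call (adjusted p = 0.0339) was lost on leaving out any library (adjusted p = 0.0712 without EC-OSB replicate 1, 0.165 without EC-OSB replicate 2, 0.0955 without RFP+ replicate 1 and 0.0657 without RFP+ replicate 2). Ifitm5 (1.00 ± 0.189 against 0.814 ± 0.0710 CPM) did not pass the test. Of 11 osteocyte genes, 4 were expressed enough to test and all 4 were higher, too few for a test of the list. Dmp1, a matrix protein of osteocytes, had 50 and 42 counts in EC-OSB and 0 in RFP+ (at least 28.8-fold higher). Phex and Ank had log2 differences of 2.82 and 0.81.

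**Figure D2:**
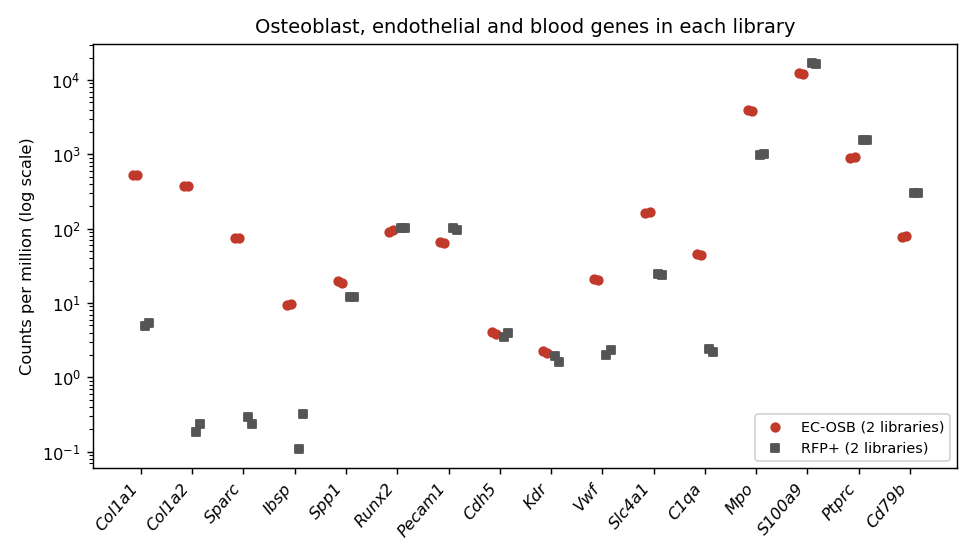
CPM (log axis) of 16 genes of bone, vessels and blood in each library, with red circles for the 2 EC-OSB libraries and grey squares for the 2 RFP+ libraries. Col1a1, Col1a2, Sparc and Ibsp lie far apart between the groups, Runx2, Cdh5 and Kdr lie close together, and S100a9 is the highest of these genes in every library.

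Matrix genes outside the osteoblast list had the largest median increase of the lists. The Col1a1 reporter also marks other collagen producers, so the gate would favour these genes too. Among 21 tested genes of fibrillar collagen and matrix, 18 were higher and 1, Col5a3, was lower. The median log2 difference was 4.82, or 4.32 with genes at 0 counts in RFP+ set to their lower bounds (camera adjusted p = 4.2e-05, or 0.240 with an estimated correlation). Most of these genes were low, with a median of 1.23 CPM in EC-OSB against 0.0453 CPM in RFP+. The list's share of counts was therefore close in both groups, 0.00905% in EC-OSB and 0.00753% in RFP+, with Col5a3 at 14.7 against 64.2 CPM. Of 20 genes that process and secrete collagen, 18 were higher and none lower (median 0.93, camera adjusted p = 3.4e-05; adjusted p = 0.240 with an estimated correlation). They include Serpinh1, the collagen chaperone (7.56 ± 0.121 against 1.04 ± 0.210 CPM), and Plod3, a lysyl hydroxylase (150.0 ± 2.02 against 119.6 ± 0.238 CPM). Basement membrane genes were split, 5 higher and 5 lower of 14 (camera adjusted p = 0.895; adjusted p = 0.744 and downward by the self-contained test fry). Nid2 was higher (2.08), and the laminin chains Lama5 (-1.64) and Lamc1 (-0.82) were lower.

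Endothelial lists went in different directions and passed fry but not camera. Fry does not set a list against other genes. With 67.2% of all tested genes called, it passed 34 of the 37 lists. A pass by fry, here and for the lists below, therefore does not set a list apart. Of 17 tested pan-endothelial genes, 9 were higher and 3 lower in EC-OSB, and 4 were at least 2-fold higher and 0 at least 2-fold lower (median 0.64, camera adjusted p = 0.106; upward by fry, adjusted p = 0.00153). Vwf, the clotting factor that platelets and their precursors also make, was at 20.8 ± 0.662 against 2.17 ± 0.266 CPM. Cd34 and Eng, both shared with blood progenitors or macrophages, had log2 differences of 0.78 and 0.85. Pecam1, an adhesion molecule also found on leukocytes, was lower (65.2 ± 2.63 against 99.2 ± 3.66 CPM). The endothelial cadherin gene Cdh5 (3.98 ± 0.216 against 3.76 ± 0.306 CPM; adjusted p = 0.668), the VEGF receptor gene Kdr (2.19 ± 0.102 against 1.79 ± 0.217 CPM; adjusted p = 0.243) and Emcn (0.424 ± 0.0252 against 0.272 ± 0.181 CPM; adjusted p = 0.249) did not pass the test. The sign for Cdh5 turned without RFP+ replicate 1 (-0.0010). Sinusoidal genes were 5 higher and 2 lower of 10 (camera adjusted p = 0.590; upward by fry, adjusted p = 0.00247). Stab2 was higher (3.41), Lyve1 lower (-0.95) and Mrc1, which macrophages share, higher (3.55). Arterial genes were 2 higher and 6 lower of 10 (median -0.60, mean 0.13, camera adjusted p = 0.151; downward by fry, adjusted p = 0.0125). Bmx (-0.95) and Cxcr4 (-0.40) were lower and Fbln5, a gene of elastic fibres, was higher (0.712 ± 0.0501 against 0.0634 ± 0.0388 CPM; log2 difference 3.45, or 4.23 without RFP+ replicate 1).

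Genes of the endothelial-to-mesenchymal transition went both ways, 7 higher and 5 lower of 13 tested (median 0.17, mean 1.24). The list was not called by camera (adjusted p = 0.798) and went upward by fry (adjusted p = 0.0155). At least a 2-fold difference was met by 3 higher and 1 lower. Vim, an intermediate filament of mesenchymal cells and leukocytes, was slightly higher (1169 ± 3.71 against 1039 ± 0.997 CPM), and the transcription factors Sox4 (-0.78) and Tcf4 (-0.50) were lower. Snai2 (6 and 4 counts in EC-OSB, 0 in RFP+) and Twist1 (16 and 9 counts, 0 in RFP+) were below the filter on low counts. BMP pathway genes were 4 higher and 6 lower of 16 (median -0.01, mean 0.56, camera adjusted p = 0.597; downward by fry, adjusted p = 0.00247). The receptor gene Acvrl1 (-0.88) and the target genes Id3 (-1.14) and Smad7 (-0.62) were lower. Bmp6 (0.348 ± 0.109 against 0.199 ± 0.0270 CPM; adjusted p = 0.184) did not pass the test, and Bmp4 had 5 and 10 counts in EC-OSB and 6 and 2 in RFP+. TGF-beta pathway genes were 6 higher and 11 lower of 20 (median -0.24, mean 0.41, camera adjusted p = 0.147). Tgfbr2 (-0.76) and Skil (-0.79) were lower and Tgfb1 (0.28) higher. Fry gave the list the opposite direction, upward (adjusted p = 0.0125). Wnt pathway genes were 5 higher and 6 lower of 21 (median -0.0020, mean 0.38, camera adjusted p = 0.808; downward by fry, adjusted p = 0.00376). Lef1 (-1.20) and Tcf7 (-1.28), which lymphocytes also use, were lower and Lrp5 (0.81) higher. Notch pathway genes fell, with 11 lower and 2 higher of 18 (median -0.41, camera adjusted p = 0.00295; adjusted p = 0.240 with an estimated correlation). Among them were Notch1 (225 ± 3.80 against 336 ± 3.90 CPM), Notch2 (-0.55) and the target gene Hes1 (-1.66).

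Secreted factors of bone and vessels changed in part. Angiogenic ligands were 8 higher (9 when adjusted over the list alone) and 2 lower of 13. Their median was 0.36 (camera adjusted p = 0.0448; adjusted p = 0.304 with an estimated correlation). Cxcl12, the chemokine of marrow niches, was at 16.8 ± 1.15 against 1.86 ± 0.243 CPM, and Fgf1 (4.35) and Angptl4 (1.21) were higher. Factors through which bone cells act on osteoclasts were 5 lower and none higher of 8 (median -0.55, camera adjusted p = 0.0229; adjusted p = 0.304 with an estimated correlation). Cxcl2 (-0.93), Ptgs2 (-0.75) and Sema4d (-0.56), genes that neutrophils and other leukocytes also express, were lower. The angiogenic call was lost without RFP+ replicate 2 (adjusted p = 0.0661) and on library totals without TMM (adjusted p = 0.0676). The call of the osteoclast factors was lost without EC-OSB replicate 1 (adjusted p = 0.132) and without RFP+ replicate 2 (adjusted p = 0.0524).

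Other mesenchymal and bone-resident cell types gave mixed lists. Osteoclast genes rose, 10 higher and 2 lower of 12 (median 1.65, camera adjusted p = 0.0113; adjusted p = 0.356 with an estimated correlation). The protease gene Ctsk was at 12.5 ± 0.0825 against 0.760 ± 0.133 CPM and Car2, a carbonic anhydrase gene shared with red cells, at 294 against 49.4 CPM, whereas Itgb3 was lower (-0.88). Cartilage genes were 9 higher and 2 lower of 14 (median 1.02, camera adjusted p = 0.128, but 0.0489 without RFP+ replicate 2; upward by fry, adjusted p = 0.00694). Col2a1 was at 2.82 ± 0.752 against 0.0542 ± 0.0252 CPM, Sox6, which red cell precursors also express, at 11.1 ± 0.686 against 1.95 ± 0.114 CPM, and Col11a2 had a log2 difference of 0.81. Marrow stromal and fibroblast genes were 9 higher and 4 lower of 15 (median 2.67, camera adjusted p = 0.22; upward by fry, adjusted p = 0.00598). Cxcl12 and Col14a1 were higher and Pi16 lower (-0.55). The share of counts of this list was lower in EC-OSB, 0.0257% against 0.0318%, with Pi16 at 192 against 281 CPM. Genes of pericytes and smooth muscle were 4 higher and 3 lower of 10 (median -0.22, mean 0.69, camera adjusted p = 0.808; 0.163 by fry). Acta2 (-0.99) and Mcam (-1.12) were lower and Myl9 was higher (2.43 ± 0.580 against 0.0901 ± 0.102 CPM; log2 difference 4.72, or 3.89 without RFP+ replicate 1 and 6.90 without RFP+ replicate 2). Adipocyte genes were 6 higher and 1 lower of 9 (median 0.79, camera adjusted p = 0.0984; upward by fry, adjusted p = 0.0125). Lpl (0.79), Cebpa (0.35) and Pparg (1.63) were higher. Skeletal muscle genes were 1 higher, Acta1 (1.14), and 1 lower, Tnnt3 (-0.52), of 5 (median -0.13, mean 0.03, camera adjusted p = 0.813; 0.771 by fry). The Tnnt3 call was lost without EC-OSB replicate 1 (adjusted p = 0.109), without EC-OSB replicate 2 (0.0669) and without RFP+ replicate 2 (0.185). Of 13 Schwann and neural genes, 4 were tested: Tubb3 was higher (1.88) and 3 were lower, among them Ngfr (-1.19) and Mbp (-0.23), too few for a test of the list.

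Genes of blood cells were among the most abundant in both groups. The most abundant genes of each group were the neutrophil granule and alarmin genes S100a9, Ngp, Ltf and S100a8, joined by Gm42418 in EC-OSB (8509 ± 560.1 against 7852 ± 511 CPM) and by Actb in RFP+ (7223 ± 67.7 against 8523 ± 93.7 CPM). Ngp was at 12506 ± 21.7 against 12420.3 ± 96.8 CPM and did not pass the test (adjusted p = 0.254). Its direction depended on the processing: it was called lower with upper-quartile factors (-0.041), a stricter filter on low counts (-0.029) and offsets for GC content and length (-0.076). It was called higher on library totals (0.062), without a filter (0.017), with limma-voom (0.0098) and without RFP+ replicate 2 (0.016), and not called under DESeq2 (-0.0049). The 16 neutrophil genes held 6.12% of counts in EC-OSB and 6.92% in RFP+. Ptprc, the common leukocyte antigen CD45, was at 909 ± 5.88 against 1563 ± 4.22 CPM. In the pan-leukocyte list, 17 of 20 genes were lower and 1 higher (median -0.32, camera adjusted p = 0.000129; adjusted p = 0.240 with an estimated correlation). The integrin chain gene Itgb2 (-0.64) and the actin bundler gene Lcp1 (-0.52) were lower.

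Red cell, platelet and macrophage genes rose in EC-OSB. Of 16 tested erythroid genes, 15 were higher and none lower (median 2.88, camera adjusted p = 2.6e-07; adjusted p = 0.240 with an estimated correlation). Slc4a1 (ENSMUSG00000006574; chromosome 11, 102348824 to 102366203, minus strand) had a log2 difference of 2.76 (SE 0.0366). Ermap was at 111 ± 0.487 against 10.8 ± 0.00133 CPM. The globin gene Hba-a2 (17.0 ± 0.237 against 15.7 ± 0.888 CPM; adjusted p = 0.113) did not pass the test, except on library totals without TMM (adjusted p = 0.0200). Megakaryocyte and platelet genes were 11 higher and 1 lower, Itgb3, of 14 (median 1.39, camera adjusted p = 0.00111; adjusted p = 0.240 with an estimated correlation). Ppbp was at 17.4 ± 0.460 against 0.154 ± 0.0650 CPM. Macrophage and monocyte genes were 16 higher and 3 lower of 20 (median 0.49, camera adjusted p = 0.000216; adjusted p = 0.337 with an estimated correlation). Their share of counts was nevertheless lower, 1.022% in EC-OSB against 1.079% in RFP+, since the abundant genes Lyz2 (5484 ± 19.3 against 6513 ± 27.4 CPM) and Itgam (1363 ± 6.32 against 1914 ± 2.88 CPM), which neutrophils also express, fell, as did Ccr2 (-0.28). These 3 were picked after their values were seen. The mannose receptor gene Mrc1 was at 85.6 ± 1.71 against 7.28 ± 0.0386 CPM and C1qc at 45.5 ± 0.879 against 2.33 ± 0.137 CPM. C1qa (ENSMUSG00000036887; chromosome 4, 136895917 to 136898803, minus strand) had a log2 difference of 4.29 (SE 0.0702). The receptor gene Csf1r, abundant in both groups, was at 360.2 ± 10.1 against 291 ± 1.77 CPM. Stem and progenitor genes were 10 higher and 2 lower of 16 (median 0.21, camera adjusted p = 0.0361; adjusted p = 0.338 with an estimated correlation). Tal1 (1.66), Gfi1b (2.18) and Kit (0.89) were higher. That call was lost without RFP+ replicate 1 (adjusted p = 0.0523), without RFP+ replicate 2 (adjusted p = 0.0545) and with the replicate number as a block (adjusted p = 0.0517).

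Lymphoid and basophil genes fell. All 15 B lineage genes were lower in EC-OSB (median -1.47, camera adjusted p = 1.8e-08; adjusted p = 0.240 with an estimated correlation). Cd79a was at 128 ± 0.865 against 366 ± 6.14 CPM. Of 16 T and NK cell genes, 14 were lower, such as Cd2 (-1.70) and Cd8a (-1.65), and 2 were higher, among them the granule protein gene Nkg7 (76.1 ± 0.706 against 30.4 ± 1.21 CPM). Their median was -0.88 (camera adjusted p = 0.000278; adjusted p = 0.240 with an estimated correlation). All 7 tested mast cell and basophil genes were lower (median -0.77, camera adjusted p = 0.00179; adjusted p = 0.240 with an estimated correlation). Prss34 was at 224 ± 0.555 against 371 ± 2.85 CPM, Hdc at 303 ± 1.96 against 459 ± 2.71 CPM and Mcpt8 at 95.2 ± 0.655 against 166 ± 0.665 CPM. Neutrophil genes divided, 5 higher and 10 lower of 16 (median -0.26, camera adjusted p = 0.128; downward by fry, adjusted p = 0.00464). The primary granule genes Elane (ENSMUSG00000020125; chromosome 10, 79886247 to 79888215, plus strand; 1056 ± 6.76 against 212 ± 2.49 CPM), Mpo (3928 ± 49.4 against 1002 ± 9.99 CPM) and Prtn3 (672 ± 6.44 against 168 ± 2.45 CPM) were higher. Mmp8 (1282 ± 1.68 against 2796 ± 4.97 CPM), Retnlg (1328 ± 12.6 against 2916 ± 40.5 CPM) and the chemokine receptor gene Cxcr2 (355 ± 2.27 against 772 ± 6.95 CPM) were lower. Mmp8, Retnlg and Cxcr2 were picked after their values were seen.

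**Figure D3:**
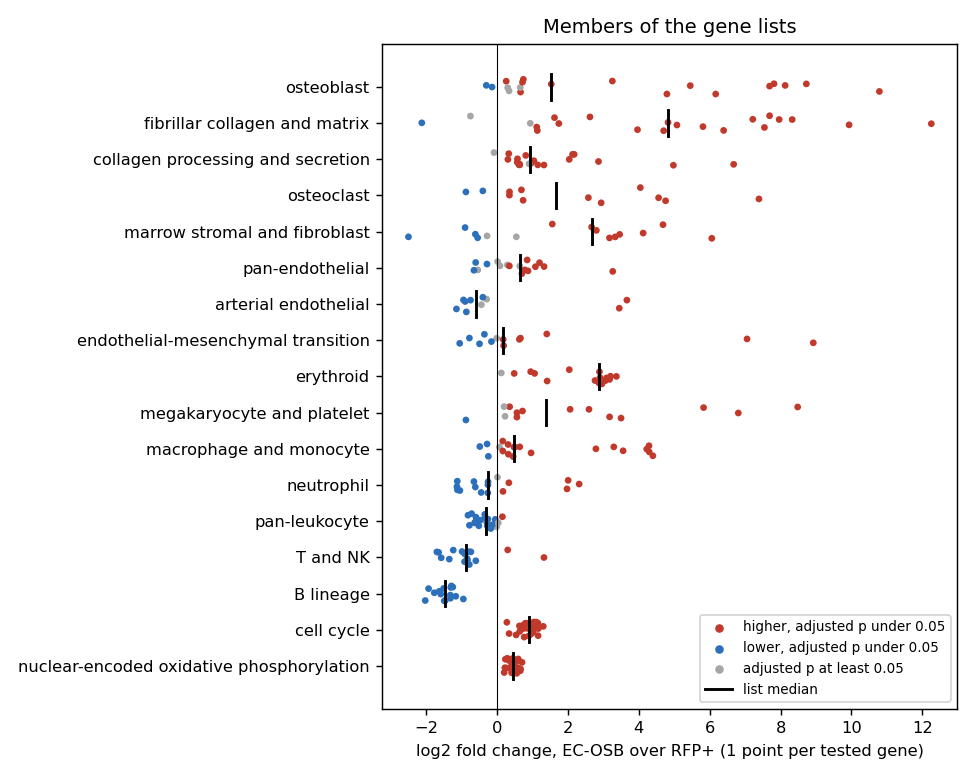
Fitted log2 fold changes of EC-OSB over RFP+ for the tested members of 17 gene lists, with each point a gene, red where it was higher, blue where it was lower and grey where it was not called, and a black bar at each list's median. Tested erythroid, cell cycle and oxidative phosphorylation genes lie above 0 and all 15 B lineage genes below it, while neutrophil genes lie on both sides. Genes at 0 counts in RFP+ appear at fitted values, which depend on the prior count.

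Genes of cell division and respiration were higher in EC-OSB. All 31 cell cycle genes rose (median 0.90, camera adjusted p = 3.5e-11; adjusted p = 0.240 with an estimated correlation). Mki67 was at 1116 ± 11.6 against 722 ± 0.0135 CPM, Top2a at 921 ± 14.7 against 552 ± 0.450 CPM and the replication helicase gene Mcm5 at 334 ± 5.62 against 171 ± 1.13 CPM. All 26 nuclear genes of oxidative phosphorylation rose by a small amount (median 0.44, camera adjusted p = 3.0e-07; adjusted p = 0.240 with an estimated correlation). Atp5b was at 775 ± 6.92 against 512 ± 4.46 CPM, and Atp5a1 and Uqcrc1 had log2 differences of 0.54 and 0.66. Of 11 tested mitochondrially encoded genes, 8 rose and none fell (median 0.42, camera adjusted p = 0.00311; adjusted p = 0.304 with an estimated correlation). They included mt-Co1 (6673 ± 50.3 against 4782 ± 24.1 CPM), mt-Cytb (0.49) and mt-Nd1 (0.56). Glycolysis genes were 12 higher and 2 lower of 19 (median 0.12, camera adjusted p = 0.0382; adjusted p = 0.304 with an estimated correlation). Tpi1 (0.77), Pfkm (1.26) and Hk1 (0.40) were higher. The glycolysis call was lost without EC-OSB replicate 1 (adjusted p = 0.0663), without RFP+ replicate 1 (0.0658), without RFP+ replicate 2 (0.0545) and with the replicate number as a block (0.0515). Genes of the unfolded protein response were 10 higher and 5 lower of 18 (median 0.19, camera adjusted p = 0.363; upward by fry, adjusted p = 0.00707). The secretory chaperone genes Pdia6 (0.64), Sdf2l1 (0.94) and Hsp90b1 (0.41) were higher.

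Stress-response, interferon and antigen-presentation genes fell. Immediate early and heat shock genes were 16 lower and 5 higher of 23 (median -0.54, camera adjusted p = 0.00163; adjusted p = 0.344 with an estimated correlation). The transcription factor genes Junb (659.8 ± 11.9 against 1153 ± 8.05 CPM) and Fos (1039 ± 1.74 against 1553 ± 7.98 CPM) and the RNA-binding protein gene Zfp36 (-0.71) were lower. Interferon response genes were 15 lower and 4 higher of 21 (median -0.23, camera adjusted p = 0.00489; adjusted p = 0.240 with an estimated correlation). Rsad2 (-0.83), Oasl2 (-0.59) and Oas2 (-0.67) were lower. MHC class II genes were 8 lower and 2 higher of 10 (median -0.69, camera adjusted p = 0.00465; adjusted p = 0.240 with an estimated correlation). The invariant chain gene Cd74 was at 488 ± 4.82 against 907 ± 9.19 CPM, and H2-Aa (-0.69) and H2-Ob (-1.80), which B cells also express, were lower. Over the 37 lists tested, camera with its preset correlation called 22, 13 higher and 9 lower, and fry called 34. With an estimated correlation 0 held, and the lowest adjusted p was 0.240. In simulated libraries a list shifted by a log2 of 0.5 was called by camera with the preset correlation (adjusted p = 1.0e-22). It was missed with the estimated one (adjusted p = 0.465), which rests on 2 residual degrees of freedom. The simulated genes were drawn independently and only that list was shifted. The simulation therefore cannot tell which correlation suits the real lists.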

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

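The assumed coefficients of variation of 10% and 20% and the offsets for GC content and length were chosen after the result was seen; the other alternatives were planned. Across them the genes differing between EC-OSB and RFP+ numbered 7602 to 10742, except 2632 (1387 higher, 1245 lower) under glmTreat and 2789 (1363 higher, 1426 lower) at an assumed coefficient of variation of 20%, which test against a larger difference and assume a larger spread. No call changed sign and stayed called, apart from 17 under the GC and length offsets. The share of higher calls ran from 47.7% with upper-quartile factors to 57.5% on library totals, against 52.9%, and no scaling moved the median difference by more than 0.0521 (log2). Leaving out 1 library gave 9582 to 9957 calls and 19 to 22 lists; the lone library was then assumed to vary like the other group. A filter of 5 CPM left 311 genes at least 2-fold higher and 328 lower, because fewer genes (10381) were tested. The first principal component held 80.04% with a prior count of 0.5; the cause was not tested.

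With the replicate number as a block (replicate block), 10536 genes and 20 lists were called; stem and progenitor genes (adjusted p = 0.0517) and glycolysis (0.0515) missed the threshold, and of the 175 genes examined only the call of Gm42418 changed, which was gained (0.12). Deviations of same-numbered libraries from their group means correlated at -0.0565 across genes. That value showed no strong shared effect of the number, but it cannot tell whether such libraries came from the same animal or sort.

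Lists past the threshold numbered 0 with an estimated correlation and 34 by fry, a self-contained test, against 22. Tek was not called under DESeq2 (0.86), limma-voom (0.84), glmTreat (0.87), an assumed coefficient of variation of 20% (0.87) or without single libraries (0.38 to 1.24; lost without EC-OSB replicate 2 and RFP+ replicate 1). The cause was not tested. Of 175 genes examined, an assumed coefficient of variation of 20% ended 54 calls, glmTreat 42, an assumed 10% 14, DESeq2 4 and any other setting at most 3; the stricter filter left 151 of them to test. Signs turned for Slc40a1 (-0.0082 with upper-quartile factors), Ngp (-0.0049 under DESeq2, -0.041 with upper-quartile factors, -0.029 with the stricter filter, -0.076 with GC and length offsets) and Cdh5 (-0.0010 without RFP+ replicate 1, at most 0.16 without another). Uncalled lists that turned were basement membrane (adjusted p = 0.744 by fry, 0.937 without TMM), TGF-beta (0.0125 by fry), and, over the libraries left out in turn, BMP (0.658 to 0.916), Wnt (0.666 to 0.983), pericyte (0.609 to 0.917) and skeletal muscle (0.658 to 0.829). The cause was not tested for these. Snai2, Twist1 and Bmp4 were below the filter on low counts. Without it, Snai2 (at least 3.13-fold higher, adjusted p = 0.0281) and Twist1 (at least 7.81-fold higher, adjusted p = 9.1e-05) were called and Bmp4 was not (adjusted p = 0.562).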

Other observations

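The tests on granulocytes, macrophages, red cells, GC content and length were chosen after the patterns were seen, and for the tests on dilution and globin genes the deciding values had been seen as well. The marker lists below were added for these tests and share no gene with the lists fixed beforehand. They were read in the same libraries in which the patterns were seen, so they are not an independent test. Bootstrap intervals below resample the genes of a list as if these were independent. They show how a median depends on the choice of genes and do not measure the spread between libraries. In EC-OSB, all 12 genes of erythroblastic island and resident macrophages were higher (median log2 difference 1.96), among them the adhesion molecule gene Vcam1 (168 ± 2.26 against 11.1 ± 0.794 CPM), the transcription factor gene Spic (7.30 ± 0.0337 against 0.443 ± 0.163 CPM), Timd4 (4.25 ± 0.599 against 0.208 ± 0.0142 CPM) and Siglec1 (39.6 ± 1.08 against 7.17 ± 0.0138 CPM). The Slc40a1 call (adjusted p = 0.0487) was lost without EC-OSB replicate 1 (0.147), RFP+ replicate 1 (0.0557) or RFP+ replicate 2 (0.331), and its sign turned with upper-quartile factors (-0.0082). Of 12 further erythroid genes, 10 were higher, such as Ank1 (64.8 ± 1.21 against 7.26 ± 0.832 CPM) and Kel (22.7 ± 0.640 against 2.97 ± 0.197 CPM), and 1, Slc25a37, was lower (143 ± 0.559 against 194 ± 1.83 CPM). Granulocyte precursor genes were 8 higher and 3 lower of 12 (median 0.52), with the granule protease gene Ctsg at 367 ± 0.298 against 107 ± 2.61 CPM, Ms4a3 at 159 ± 4.29 against 37.5 ± 0.736 CPM and Fcnb at 282 ± 1.27 against 81.9 ± 0.284 CPM, and Hp lower (864 ± 3.69 against 1019 ± 11.0 CPM). Mature neutrophil genes were 11 lower and 1 higher of 12 (median -0.69), with Fpr1 at 94.9 ± 0.821 against 197 ± 1.75 CPM, Clec4d at 68.7 ± 2.10 against 129 ± 2.47 CPM and Il1b at 223 ± 3.57 against 348 ± 3.21 CPM. The members named were picked after their values were seen.

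Of 13 mitochondrially encoded genes, 6 had few counts for their kind, at most 103 in any library, where each of the other genes had at least 23599. Among the 6 were mt-Co2 (88 and 90 counts in EC-OSB, 72 and 62 in RFP+) and mt-Atp6 (74 and 71 in EC-OSB, 60 and 79 in RFP+). The cause was not tested.

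Blood lineages moved apart between the groups. Osteoblasts diluting a common blood mixture would lower all lineages alike, but the erythroid median lay 4.35 (log2) above the B lineage median (95% bootstrap interval over genes 2.73 to 4.54), and 4.26 above it after a trend on GC content and transcript length was removed (2.79 to 4.55). These values argue against both dilution and bias along that trend as the whole cause. A candidate explanation is that the EC-OSB gate held more erythroid cells and resident macrophages: the smaller median of the added lists was 1.96 (0.64 to 2.65). The gene of each added list most abundant in EC-OSB changed less: Tfrc was at 244 against 140.0 CPM and Slc40a1 at 218 against 211 CPM. Slc25a37, the added erythroid gene most abundant in RFP+, was lower in EC-OSB, at 143 against 194 CPM. The 4 globin genes, main products of red cells, also rose less, by a median of 0.71 (range of these genes 0.12 to 1.06). Hbb-bs, the most abundant, was at 94.0 against 67.3 CPM and Hba-a2 at 17.0 against 15.7 CPM. Counts of genes with near-identical copies are uncertain, so the erythroid part stays open. Of the 12 genes in each list, 7 macrophage and 6 erythroid genes stood at 10 CPM or more in RFP+ cells too, and a gate on Col1a1-GFP would remove such cells unless they carried green signal or stuck to green cells, which was not tested. Different red-labelled ancestors of the sorted cells, as the design names them, stay open and untested.

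Neutrophil granule genes moved in opposite directions. After a trend on GC content and length was removed, Mpo, Elane and Prtn3 still lay 3.11 (log2) above Mmp8, Mmp9 and Retnlg, against 3.13 before. In the added lists, written after this pattern was seen, the precursor median then exceeded the mature median by 1.25 (95% bootstrap interval over genes 0.64 to 2.47). These values argue against bias along that trend as the whole cause. Earlier granulocyte stages in the EC-OSB gate are a candidate explanation. Before that removal the precursor median exceeded the mature median by 1.21 (95% bootstrap interval over genes 0.54 to 2.50). The difference was 1.28 without Chil3, which had been seen before among abundant genes. In RFP+ cells 12 of the precursor and 11 of the mature genes stood at 10 CPM or more. Both groups therefore expressed nearly all of these genes. A gate on Col1a1-GFP would remove either stage unless the cells carried green signal or stuck to green cells, which was not tested. The 16 neutrophil genes of the fixed list nonetheless held 6.12% of counts in EC-OSB, against 6.92% in RFP+. Whether the shift lies in the proportions of stages or in expression within a stage was not tested.

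Nuclear genes of oxidative phosphorylation rose together by a small amount. Their median log2 difference was 0.36 (95% bootstrap interval over genes 0.30 to 0.48) after removing the trend on GC content and length. Before removal it was 0.44, and 26 of 26 genes stayed above 0 afterwards. These values argue against bias along that trend as the whole cause. GC content and length were known for 98.8% of tested genes. The correlation of the fold change across genes was 0.02 with GC content and -0.05 with length (Spearman). The removed trend was small, from -0.126 to 0.0936 (log2, 5th to 95th percentile), and could not have moved any of the medians far. The tests on GC content and length therefore cover only bias that follows this trend across genes. Dividing or red cell precursors, which moved with the same group, stay open as sources and were not tested apart from it.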
